A study of Mus musculus with 2 samples.

How the data were processed

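H3K27me3 ChIP-seq was made on 2 pools of mouse hearts at embryonic day 15.5, of 78 and 62 embryos of both sexes, each with 2 technical replicates combined into 1 library record and a size range of 300 to 500 bp, per the labels. The 2 pools were labelled as biological replicates 1 and 2 of a single group, and no other group was present.

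The authors deposited peak lists in narrowPeak format on the mm10 build, per the labels. Each replicate had its own list, and there was a list called on both replicates together and a list of replicated peaks derived from the other 3, per the deposited file records. The peak caller, its threshold, the control libraries and the rule for a replicated peak are not given in the sources used here. A promoter marked by a replicated peak is therefore not one shown to be marked in each pool, and the marks in the replicates' own lists are given beside it. The deposited file records name more further input files for replicate 1 than for replicate 2 without saying what they are. Each peak carries a signal value computed by the authors, whose scaling is not stated, and −log10 p and −log10 q values computed by the authors. These scores were used only to rank and filter peaks within their own list. Every deposited peak had a −log10 p above 2, and 64.3% of the peaks of replicate 1, 65.4% of those of replicate 2 and 92.1% of the replicated peaks had a −log10 q of 2 or more. Read counts were not used here, so the depth per sample is unknown and no interval that needs it is given. A shallower or noisier library gives fewer or more fragmented peaks, so numbers and lengths of peaks of the 2 replicates are not measures of the amount of the mark.

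Genes and sequence were taken from the GENCODE M21 annotation and the GRCm38 assembly, the build of the files. The match was checked by position: no peak lay on another chromosome than 1 to 19 and X, past a chromosome end or in a leading run of unknown bases. The 21728 protein-coding genes on these chromosomes with a unique symbol were used. The TSS was the 5′ end of the gene record, which can differ from the start used in the heart; any of 93155 annotated transcript starts was an alternative. A promoter was the TSS ± 1 kb, and it was marked when a replicated peak overlapped it by 1 bp or more. The covered share of a gene was the percent of TSS ± 2.5 kb covered by peaks. It is given for the replicated list and as mean ± SD over the own lists of the 2 replicates.

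Overlap of the replicates was the share of peaks with at least 50% of their length covered by the other list, with the shared length over the union. The chance level came from 100 circular shifts of one list within each chromosome, which keep the spacing of peaks but not their relation to genes. The same shifts gave the chance level for promoters and genome parts, where promoters took precedence over exons and exons over introns. The 12 gene lists were fixed before the data were examined, and all their members were found in the annotation. Each list was set against all other protein-coding genes with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 12 lists, and 4 pairs of lists were tested against each other with adjustment over the 4 tests. The threshold was 0.05. Exact (Clopper-Pearson) 95% intervals of marked shares cover the sampling of genes only. The CpG ratio of marked and unmarked promoters was compared with a two-sided permutation test of 100000 resamples. Promoters were CpG-rich at a ratio of 0.6 or more and a GC fraction of 0.5 or more. Domains were replicated peaks merged across gaps of up to 3 kb.

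Named genes followed a rule fixed before the data were examined: in each list the 4 marked members with the largest covered share, or all where 5 or fewer were marked, and the first 2 unmarked members in list order; protein-coding genes with a TSS in the 10 longest domains; the 10 genes outside the lists with the largest covered share; and the 5 genes in each direction with the largest difference between the replicates. Further genes named in the closing section were chosen after their values were seen. There, lists were also compared between the replicates with 10000 random lists, in which each gene was replaced by 1 of its 40 nearest genes in covered share and CpG ratio. A further matching added the covered share of TSS ± 10 kb in the joint list, and another drew on 20 near genes among other transcription factors, found by 101 symbol stems; 1 more stem was dropped after the values had been seen.

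Alternatives fixed before the data were examined were other promoter windows, 500 bp of covered promoter, any transcript start, a −log10 q of 2 or more, the upper 50% of replicated peaks by the authors' p, the list called on both samples together, the intersection of the replicates' own lists, a CpG-rich background, other gaps and overlaps, and each replicate's own list in place of the replicated one, which is the setting without the other replicate. With 1 group of 2 replicates, no test across samples, no paired analysis and no count of other sample splits was possible. The code was run on simulated data first. Of 2 simulated lists of 20000 peaks built to share 40% of peaks, 40.0% was found. Of 500 random lists of 20 genes drawn from the 21728 genes 3.4% had an unadjusted p under 0.05, and 98.5% of such lists marked at 60% against a background of 17% were called. Of unchanged lists compared with matched random lists, 4% fell outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with a fixed random seed of 11.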

Results

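Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 trimethylated at lysine 27 (H3K27me3), the mark laid down by Polycomb repressive complex PRC2, in the mouse heart at embryonic day 15.5. The series held 1 group of 2 biological replicates of mixed-sex hearts from the B6NCrl strain. Replicate 1 was a pool of hearts from 78 embryos and replicate 2 a pool from 62 embryos. The deposited files were 4 peak lists on the mm10 genome build: the own list of each replicate, a list called on both samples together, and a list of replicated peaks. Replicate 1 had 96560 peaks covering 46.9 Mb and replicate 2 had 57467 peaks covering 32.1 Mb, a mean of 39.5 ± 10.5 Mb (SD, n = 2). The replicated list had 45446 peaks covering 43.1 Mb, or 1.69% of the sequenced bases of chromosomes 1 to 19 and X, with a median length of 538 bp. The files hold no read counts, so sequencing depth is unknown. With 1 group, the design implies no comparison between conditions. The questions were which genes and regions carried the mark in this tissue and how far the replicates gave the same answer.

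Promoters of Hox genes, neural and endoderm transcription factors and developmental ligands carried the mark in the heart with few exceptions, while promoters of the housekeeping genes did not. A promoter was called marked when a replicated peak overlapped the 1 kb on either side of the transcription start site (TSS). All 39 Hox cluster genes, which set positional identity along the body axis, were marked, as were all 30 neural transcription factors. Of the endoderm transcription factors 17 of 18 were marked, and of the developmental ligands 19 of 20. Replicated peaks covered the whole TSS ± 2.5 kb of the neural factors Ascl1 (chromosome 10, 87490819 to 87493660), En2, Fezf2 and Lhx2. The own peaks of the replicates covered 98.5% ± 2.19 (SD, n = 2) of that window at Fezf2 and 96.9% ± 1.16 at Lhx2. Cdx2, a master regulator of intestinal fate, Foxa2, Mnx1 and Neurog3, which starts the pancreatic endocrine programme, were covered throughout, with 99.3% ± 0.976 at Cdx2 and 92.9% ± 4.06 at Foxa2 in the replicates' own peaks. The same held for the secreted signals Shh (chromosome 5, 28456815 to 28467256), Ihh, Fgf3 and Gdf7, with 100% ± 0.0 at Shh and 98.9% ± 1.58 at Fgf3. The unmarked members of these lists were Hnf4a, a nuclear receptor of liver and gut, and Fgf20. None of the 24 housekeeping genes, among them Actb and Gapdh, was marked, which allows a share of up to 14.2% by the exact 95% interval.

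In all, 3791 of 21728 protein-coding genes (17.4%) had a marked promoter, against a mean of 847 and a maximum of 1016 in 100 circular shifts of the replicated peaks. The own lists of the replicates marked 4415 and 3751 genes, a mean of 4083 ± 470 (SD, n = 2), and 3432 genes were marked in both. By two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 12 lists, the Hox list differed with an adjusted p of 2.73e-29, the neural factors with 9.75e-23, the ligands with 2.52e-13 and the endoderm factors with 5.64e-12. Each of these 4 lists had the same number of marked members in both replicates. The housekeeping genes lay below the other genes with an adjusted p of 0.0196 by the same exact test, a call that was lost under 4 of its 11 alternative settings. Genes are the units of these tests, not replicates, and neighbouring genes such as those of a Hox cluster share domains, so the p-values overstate the number of independent observations.

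**Figure D1:**
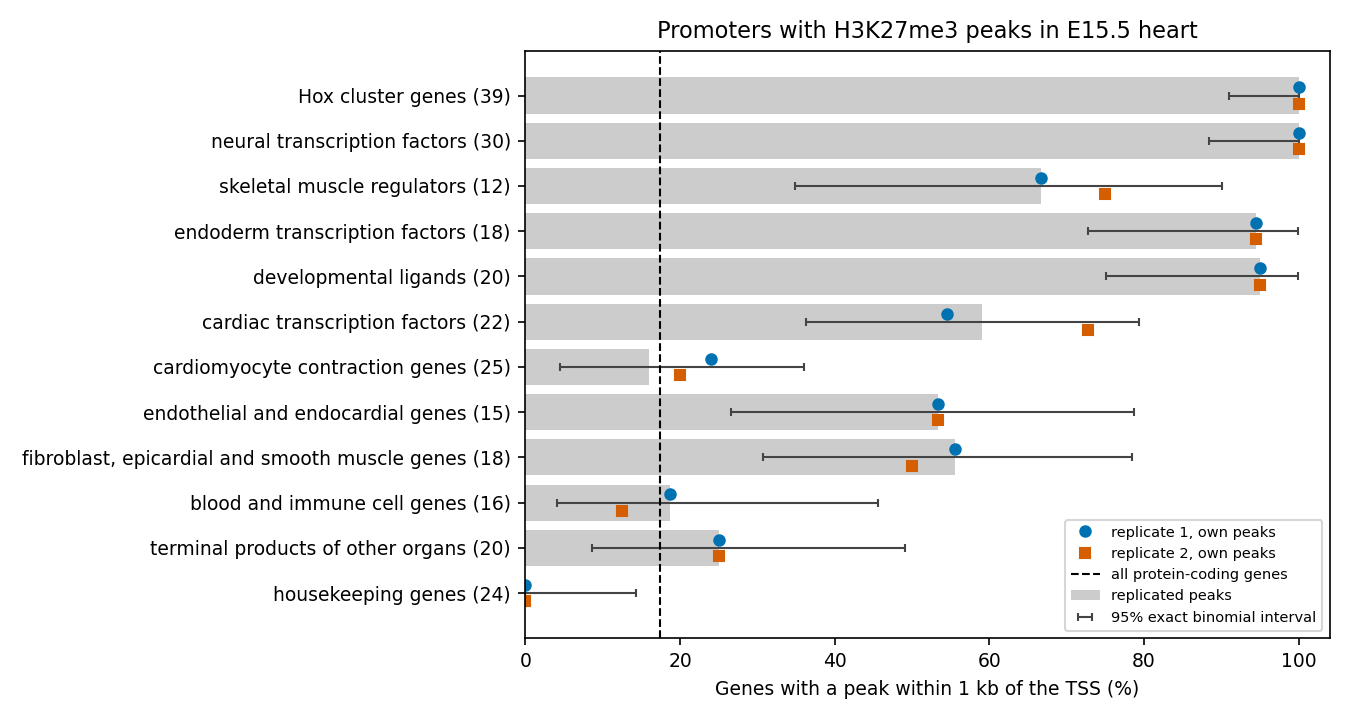
Share of each gene list's members (number of genes in parentheses) with an H3K27me3 peak within 1 kb of the TSS, in percent. Grey bars show the replicated peaks with their exact 95% binomial interval, blue circles and orange squares show the own peak lists of replicates 1 and 2, and the dashed line marks the 17.4% of all protein-coding genes. The Hox and neural lists lie at 100% and the housekeeping list at 0%, with the cardiac transcription factors at 59.1%.

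Transcription factors of the heart itself were marked less often than those of the nervous system and ranged from almost fully covered to uncovered. Of 22 cardiac transcription factors 13 were marked. The most covered were Irx4 (chromosome 13, 73260479 to 73269608), a ventricular homeobox factor, Hand1, Tbx1 and Tbx2. Replicated peaks covered 98.4% of the TSS ± 2.5 kb of Irx4, 94.8% of that of Hand1, 93.7% of that of Tbx1 and 91.0% of that of Tbx2. The own peaks of the replicates covered 90.8% ± 9.71 (SD, n = 2) at Irx4 and 92.6% ± 0.537 at Hand1. Gata4 (chromosome 14, 63198922 to 63271692) and Gata6, zinc finger factors of the cardiac programme, were unmarked, with replicate means of 1.95% ± 2.76 and 0.0% ± 0.0, although replicate 2 on its own had a peak at Gata4. The Gata4 window lay at the 5′ end of the gene record, with a CpG ratio of 0.174, and may not hold the start used in the heart. Against all other genes the cardiac list was marked more often (59.1% against 17.4%, adjusted p = 3.36e-05, Fisher's exact test). Set directly against the 30 neural factors it was marked less often, a difference of -40.9 percentage points with an adjusted p of 0.00027 over the 4 list-against-list exact tests. The difference from the endoderm factors was -35.4 points (adjusted p = 0.0169, Fisher's exact test). That call was lost with the own peaks of replicate 2, in which 16 cardiac factors were marked against 12 in replicate 1 (-21.7 points, adjusted p = 0.14 by the same exact test). It was also lost with the TSS ± 2.5 kb and with the list called on both samples together.

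Genes for the contractile machinery of cardiomyocytes were mostly unmarked. Of 25 members 4 were marked: Nebl, which encodes a Z-disc protein, Ryr2, the calcium release channel of the sarcoplasmic reticulum, Myl7, the atrial myosin light chain, and Myl2, its ventricular counterpart. Covered shares were 66.0% at Nebl, 29.2% at Ryr2, 16.1% at Myl7 and 5.28% at Myl2, whose window was marked in replicate 1 only. The myosin heavy chains Myh6 and Myh7 were unmarked. The share was 24% and 20% in the replicates' own lists and 36% in the list called on both samples together. Over the alternatives its difference from other genes ran from -6.83 to 20.8 points. The highest value came from the CpG-rich background, which left only 5 contraction genes, 2 of them marked. The share of 16.0% did not differ detectably from that of other genes (adjusted p = 1.0, Fisher's exact test) or from the 25% of terminal products of other organs (5 of 20, difference -9.00 points, adjusted p = 0.482 by the exact test between the lists). Those terminal products included the marked Krt1 and Lor of the epidermis, Gfap of astrocytes, Sftpc of the lung and Apoa1 of the liver, and the unmarked Alb and Fga. By the replicates' own lists the Gfap promoter was marked in replicate 1 only. The terminal products too did not differ detectably from other genes (adjusted p = 0.45, Fisher's exact test). Neural transcription factors and terminal products of other organs differed by 75 points, with an adjusted p of 2.76e-08 by the exact test between the lists. Blood and immune genes were marked in 3 of 16 cases (C1qa, Klf1 and Mpo; adjusted p = 0.819, Fisher's exact test), with Ptprc and Spi1 unmarked. The Mpo promoter was marked in neither replicate's own list.

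Endothelial and endocardial genes, and fibroblast, epicardial and smooth muscle genes, were marked more often than other genes. Of 15 endothelial and endocardial genes 8 were marked, led by Sox18 (chromosome 2, 181669836 to 181671640), Cldn5, Flt1 and Erg, with 100%, 88.9%, 83.0% and 80% of the window covered by replicated peaks. Pecam1 and Cdh5, which encode endothelial junction proteins, were unmarked. Of 18 fibroblast, epicardial and smooth muscle genes 10 were marked, led by Tcf21 (97.8% covered), Myh11 (93.5%), Wt1 (90%) and Aldh1a2 (89.6%), while Upk3b and Col3a1 were unmarked. By Fisher's exact test the adjusted p was 0.00256 for the endothelial list and 0.000493 for the fibroblast, epicardial and smooth muscle list. The libraries were made from pooled hearts, so the cell type that carried a peak is unknown. A marked gene is not shown to be marked in the cells that express it, and this holds for every list. The skeletal muscle regulators were marked in 8 of 12 cases (adjusted p = 0.000432, Fisher's exact test). Pax3, Pax7 and Pitx1 were covered throughout, and the replicates' own peaks covered 96.4% ± 0.99 at Myod1. Myf5 (chromosome 10, 107482908 to 107486134) and its neighbour Myf6 had no covered base in the window in either replicate.

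Genes of all 4 Hox clusters lay in domains that were among the 5 longest; Hoxb13 was marked but lay outside the HoxB domain. Replicated peaks merged across gaps of up to 3 kb gave 15107 domains with a median length of 1421 bp, of which 1537 were 10 kb or longer and held 52.5% of the domain length. With gaps of up to 1 kb 903 domains were that long and held 33.9%, with gaps of up to 5 kb 1945 held 63.5%, and the list called on both samples together gave 2709. The longest, of 263.5 kb, spanned the HoxC cluster from Hoxc13 to Hoxc4 (chromosome 15, 102887944 to 103151451), and own peaks of replicates 1 and 2 covered 88.5% and 86.2% of it. The HoxA cluster with Evx1 lay in a domain of 222.6 kb (chromosome 6, 52110434 to 52332985), HoxB genes from Hoxb9 to Hoxb1 in one of 203.1 kb (chromosome 11, 96228712 to 96431814), and the HoxD cluster with Evx2 in one of 133.6 kb (chromosome 2, 74643339 to 74776971). The third longest domain, of 206.5 kb, lay over Cdh22, a cadherin gene, and 1700025C18Rik (chromosome 2, 165062253 to 165268708). The rest of the 10 longest covered the TSSs of Rhcg, Sipa1l3 and the myogenic regulator Pax7, and 2 adjacent regions of chromosome 9 without a protein-coding TSS. The first of these (61250370 to 61368555) overlapped the long noncoding RNA gene B930092H01Rik, and the second (61373802 to 61499432) overlapped the gene Tle3. Outside the fixed lists, 208 genes had a window covered throughout by replicated peaks. Those with the most covered bases in TSS ± 10 kb among them were Gm4881, Crlf1, Gm28308, Zic2, Foxf1, Cdh22, Gm28230, 5730596B20Rik, Hmx1 and Vax2. Gm28308 and 5730596B20Rik lay in the HoxA domain, Gm28230 in the HoxD domain and Cdh22 in the third longest. Their windows therefore repeat coverage already described. The number of domains rose to 30656 in the own peaks of replicate 1, which held many short isolated peaks.

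**Figure D2:**
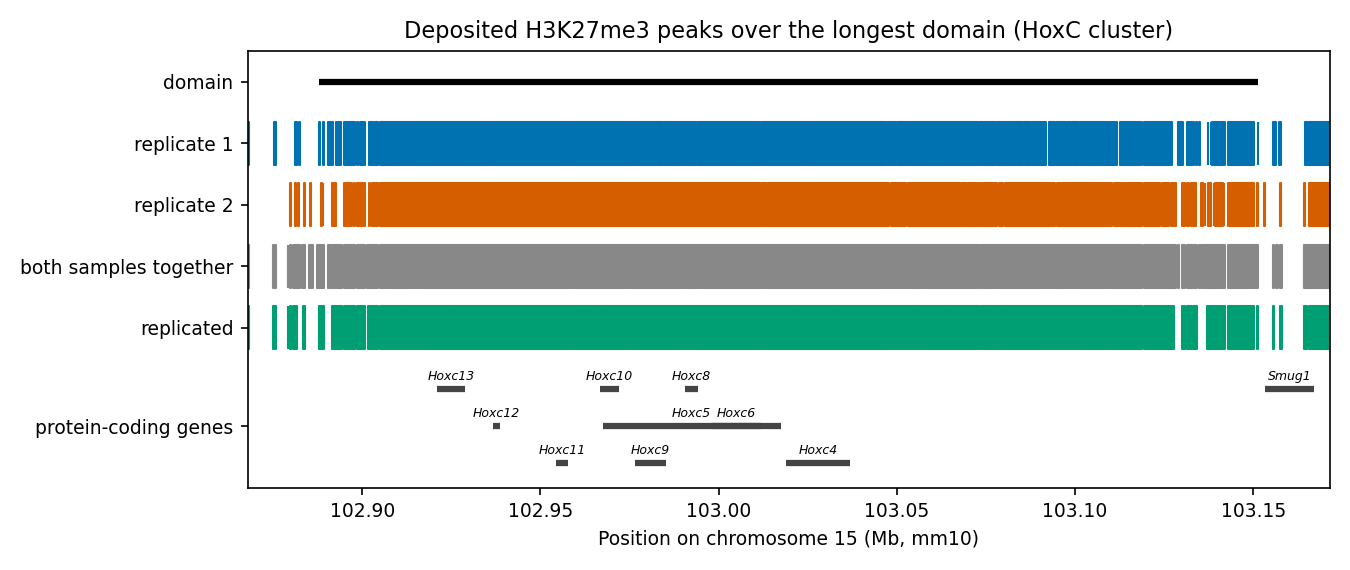
Map of the longest domain and 20 kb on either side on chromosome 15 (position in Mb, mm10). Coloured blocks are peaks of the 4 deposited lists, the black line is the domain of 263.5 kb, and dark lines are protein-coding genes. The peaks of all 4 lists cover most of the domain, with 88.5% and 86.2% covered by the own peaks of replicates 1 and 2.

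The replicates shared most of their peaks with the smallest p, which were also the longest, and differed in those with larger p. At least 50% of the length was covered by peaks of the other replicate in 58.0% of the peaks of replicate 2, against a chance level of 1.99% and a maximum of 2.97% in 100 circular shifts. For the longer list of replicate 1 the share was 29.3%, against 1.38% by chance. The shared length of 23.3 Mb was 41.8% of the union, against 0.866% by chance. Each list was ranked by the authors' p and cut into 10 classes of equal size. In the class with the smallest p, 87.2% of replicate 1 peaks and 98.4% of replicate 2 peaks were found in the other list. In the class with the largest p the shares were 11.3% and 37.8%. Median peak lengths in these 2 classes were 1140 and 230 bp in replicate 1, and 1516 and 245 bp in replicate 2. The parts of p and of length in the sharing were not separated. All 45446 replicated peaks were identical to peaks of the list called on both samples together, and 20040 of them (44.1%) were covered to at least 50% in both replicates' own lists. A further 35.2% were so covered in replicate 1 only, 12.4% in replicate 2 only and 8.29% in neither. A replicated peak was therefore not always covered to 50% by each replicate's own peaks. Where an overlap of 50% of either peak was enough, 28886 replicated peaks (63.6%) had it in both replicates' own lists. Of the peaks called on both samples together but not kept as replicated, 0 had it. Among genes, the covered share of the TSS ± 2.5 kb was most in excess in replicate 1 at Adgrg1 (58.4% against 9.08%), Cds1 (89.8% against 40.5%), Cd7, Cldn11 and Mmel1. It was most in excess in replicate 2 at Rbm20, a regulator of titin splicing (51.2% against 10.7%), Tcf20 (64.6% against 28.7%), P2ry2, Ptprz1 and Casz1.

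**Figure D3:**
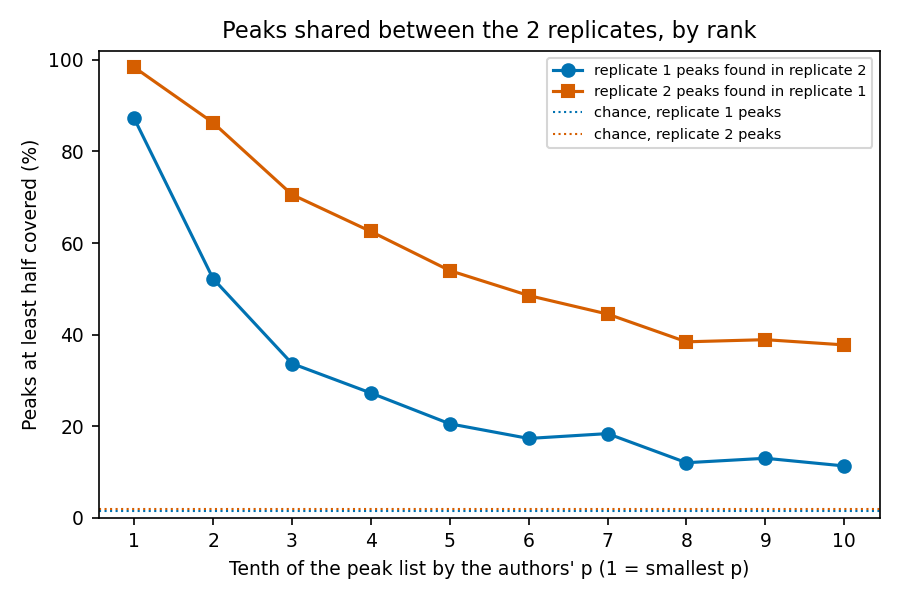
Percent of the peaks of one replicate with at least 50% of their length covered by peaks of the other, in 10 equal classes of the list ranked by the authors' p (class 1 holds the smallest p). Blue circles are replicate 1 peaks and orange squares replicate 2 peaks, and the dotted lines are the means of 100 circular shifts. The shares fall from 87.2% to 11.3% and from 98.4% to 37.8%.

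Promoters held 10.8% of the length of replicated peaks and 1.60% of the sequenced bases, a 6.78-fold excess that no circular shift reached (highest 2.12%). Exons outside promoters held 8.66% against 3.37% of the bases. Introns held 36.5% against 36.2%, and intergenic sequence held 44.0% against 58.8%. In the replicates' own peaks, promoters held 9.38% of the length in replicate 1 and 12.1% in replicate 2.

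Marked promoters had a higher median ratio of observed to expected CpG dinucleotides in the TSS ± 500 bp than unmarked ones, 0.602 against 0.533. Their ratios were also less spread, with quartiles of 0.42 and 0.743, against 0.194 and 0.775 in unmarked promoters. The upper quartile was thus higher in unmarked promoters. The difference in medians of 0.0691 had a p of 1e-05 in a two-sided permutation test over genes, the smallest that 100000 resamples can give. It fell to 0.0257 (permutation p = 0.02 with 1000 resamples) when the own peaks of replicate 1 were used. CpG-rich promoters made up 49.3% of the marked and 43.8% of the unmarked promoters, but 45.3% and 44.6% with the own peaks of replicate 1. Restricting both the lists and the background to CpG-rich promoters kept the higher share in every list that had it against all genes, with adjusted p from 6.98e-17 for the Hox genes to 0.0107 for the fibroblast, epicardial and smooth muscle genes by Fisher's exact test. This left 24 Hox genes but only 4 endothelial and 3 fibroblast, epicardial and smooth muscle genes, all of them marked.

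The X chromosome had 11.0 replicated peaks per Mb, 0.602 times the autosomal 18.2. Chromosome 3 was lowest among the autosomes with 9.06 peaks per Mb and chromosome 11 highest with 31.1. By length, 7.55 kb per Mb of the X chromosome was covered, below the lowest autosome at 8.52 kb per Mb. The ratio of X to autosomal density was 0.662 in the own peaks of replicate 1 and 0.514 in those of replicate 2. In the list called on both samples together it was 0.811, and 13.7 kb per Mb of the X chromosome was covered, above the lowest autosome at 11.4 kb per Mb. Both pools held male and female embryos, so the X chromosome had fewer copies than an autosome in each, and these densities were not corrected for it. No test was made of this description.

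**Figure D4:**
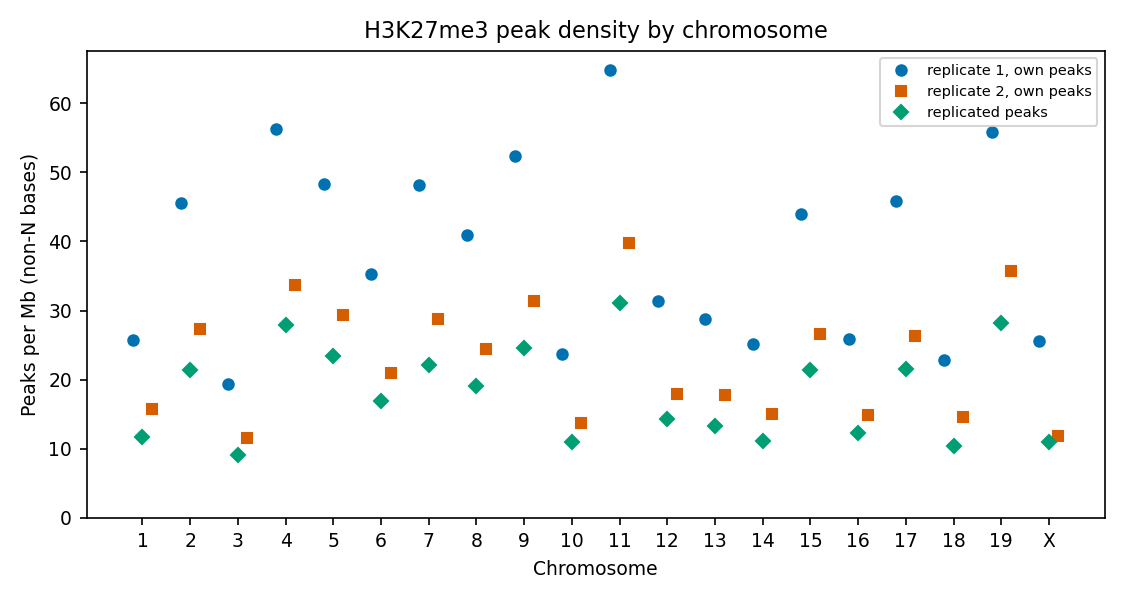
Peaks per Mb of non-N sequence on each chromosome for the own peaks of replicate 1 (blue circles), replicate 2 (orange squares) and the replicated peaks (green diamonds). The replicated peaks range from 9.06 per Mb on chromosome 3 to 31.1 on chromosome 11, with 11.0 on the X chromosome.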

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

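All tests of the X chromosome in this part were chosen after its density of peaks had been seen, and those on the ratio of the replicates after their own values had been seen. The list called on both samples together held 56822 peaks that were not kept as replicated, 55.6% of that list, and the report's gene and domain counts leave them out. Their median length was 247 bp, against 538 bp for the peaks kept, and 23141 of them touched no peak of either replicate's own list. Of these peaks, 3571 lay on the X chromosome.

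Peaks on the X chromosome made up 3.95% of the replicated list and 6.28% of the joint peaks not kept, and their density relative to the autosomes was 0.602 in the former and 0.983 in the latter. Of the joint X peaks 33.4% were kept, against 41.3% to 47.4% on the 19 autosomes. Lower p ranks and shorter peaks go with much of this, since autosomal peaks of the same p rank and length would be kept at 36.0%. X peaks were still kept less often by -2.54 percentage points, outside the autosomal range of -0.996 to 1.02. The autosomes themselves set the expected rate, which draws their own deviations towards it, and p can still differ within a class. The comparison therefore cannot decide whether weak scores are the whole cause. Fewer genes on the X chromosome, in particular 1.38 CpG-rich promoters per Mb against an autosomal minimum of 2.68, may account for part of the low density, since 22.6% of these promoters were marked, inside the autosomal range of 12% to 25.1%; it had 5.80 protein-coding genes per Mb (chromosome 12 had 5.5 genes and 14.2 peaks per Mb, chromosome 18 had 5.83 and 10.4, chromosome 3 had 6.42 and 9.06), its 7.94 peaks per CpG-rich promoter lay above the autosomal 2.87 to 6.29, and 11.9% of all its promoters were marked, under the autosomal minimum of 13%. Replicate 1 had 2.15 times as many X peaks as replicate 2, outside the autosomal range of 1.57 to 1.74. The ratio was still 1.32 with the same number of peaks from each list (autosomes 0.932 to 1.04), which argues against the number of peaks alone. Cutting a list by p does not reproduce a library of lower depth. Joint X peaks had a median −log10 p of 4.22, against 4.65 to 5.05 on the autosomes. Lower depth in replicate 2 and a different share of male and female embryos in the 2 pools stay open, because the files give neither the sex ratio nor the depth. The lower X copy number of any pool of both sexes was not corrected for, and its part in the low density was not tested.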

How the results depend on the processing

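Of the 205 alternative values of the main results, 193 stayed the same. This meant the same side of a threshold or within the SD of the replicates. For numbers of marked promoters and domains it meant within a fixed ratio of the main value. The SD came from the replicates alone, and their own lists were among the alternatives, so staying within it is a weak check. For the peak overlap it was the SD of 29.3% and 58.0%. A fall of the replicate 1 share from 29.3% to 19.8% thus counted as the same. No called difference reversed. Differences that were not called could change sign: contraction genes (-6.83 to 20.8 points) and blood genes (-7.53 to 3.97) against other genes, and contraction genes against terminal products (-12 to 7). For 11 of the 12 lists the call was the same under every alternative run. The tests on the cardiac factors between replicates and on the named genes were chosen after the results had been seen. Housekeeping genes stayed lower but lost the call with the TSS ± 500 bp (-14.8 points), 500 bp of covered promoter (-13.8), the upper 50% of peaks by p (-14.2) and the intersection of the replicate lists (-14.8), with adjusted p from 0.00731 to 0.089 over all alternatives. The difference of cardiac from endoderm factors lost its call with the TSS ± 2.5 kb (-26.3 points), with the list called on both samples together (-26.3), and without replicate 1, where the range over the replicates left out was -39.9 to -21.7 points; its adjusted p ran from 0.00577 to 0.14. The cause was not tested. Reciprocal overlap of at least 50% lowered the shared peaks of replicate 2 to 33.3%, and the other settings gave 48.8% to 68.6%. The promoter share of peak length was 24.7% with the wider promoter, which covers more bases by construction, and 8.83% in the list called on both samples together. That list gave 28829 domains, and leaving out a replicate gave 17820 to 30656, against 15107. Marked promoters numbered 2993 to 4699 over the alternatives. The covered share of 283 list members and named genes was followed under 3 other lists, and 575 of 849 values lay within the SD of the replicates. Here too that SD came from the replicates' own lists, which were among the 3. The joint list, which holds every replicated peak and so cannot lower a share, raised it in 55 genes. The CpG-rich background could not be applied to the blood list or the terminal products, which have no CpG-rich member. Unknown depth limits any reading of the longer list of replicate 1.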

Other observations

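Gene families were compared by the letters that begin their symbols, a grouping chosen after the peak lists had been seen, with the same exact test and adjustment over 151 families of 15 or more members. The mark was more frequent than in other genes in 16 families and less frequent in 13, 3 of these calls lying at an adjusted p of 0.05 when rounded. Among CpG-rich promoters alone, 9 of the 16 and 5 of the 13 kept their call; the Olfr family has no CpG-rich member and the Vmn family 1. All 19 Wnt genes, which encode secreted signals, were marked (adjusted p = 1.90e-13, Fisher's exact test), as were 15 of 17 Syt genes, the calcium sensors of vesicle release (1.49e-08), 26 of 45 Col genes, the collagens (4.14e-08), 12 of 19 Sox factors, 11 of 16 Pou factors and 10 of 15 Kcnj genes for inward rectifier potassium channels. Keratin genes were marked in 19 of 53 cases although none had a CpG-rich promoter. At the other end, 14 of 1134 Olfr genes, the odorant receptors, and 0 of 330 Vmn genes, the vomeronasal receptors, were marked (8.35e-73 and 3.08e-26). Also below other genes were 0 of 49 Mrpl genes for mitochondrial ribosomal proteins and 1 of 54 Rpl genes (0.00198 and 0.00689), while the related Mrps (1 of 29, 0.145) and Rps genes (2 of 44, 0.0837) missed the threshold. Genes are again the units, and members of a family can be neighbours, as the 53 keratin genes lay on 2 chromosomes. These p-values too overstate the number of independent observations. Reads were not examined, so a missing peak among similar genes is not shown to be a missing mark.

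CpG-rich promoters were more frequent mainly where more than 75% of the TSS ± 2.5 kb was covered by replicated peaks. They were 40% of the 703 genes covered to 10% or less, and 42.9% to 46.2% in the classes from above 10% to 75%. Their share was 54.9% at above 75% to 90%, and 69.6% in the 780 genes covered to more than 90%. Among genes with no covered base it was 43.6%. Of the 983 promoters marked in replicate 1 only, 26.3% were CpG-rich, against 40.4% of the 319 marked in replicate 2 only and 50.7% of the 3432 marked in both.

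All tests of the next pattern were chosen after it had been seen, including the 3 ways of matching random lists, and 1 of the symbol stems that define other transcription factors was dropped after values had been seen. Cardiac transcription factor promoters were more covered in replicate 2 although its peak list was shorter: 13 of the 17 members with any covered base were higher in replicate 2, such as Nkx2-5 (66.8% against 35.3%) and Tbx5 (24.8% against 0.0%), and Tbx2 went the other way (62.4% against 89.2%). Over these 17 members replicate 2 led by 7.31 points. It led by 4.00 points over the 19 members covered in TSS ± 10 kb, and by 6.15 points over the 15 covered with a −log10 q of 2 or more. Over all 22 members the mean covered share was 33.6% in replicate 1 and 39.3% in replicate 2. More complete calling at regulators in general would raise other transcription factors too. Their 10000 matched lists had a mean of -3.31 points (central 95% -7.65 to 1.19), which argues against it, but not against such calling at some regulators. The cardiac list lay at a percentile of 100 among them (100 also with both other matchings). That percentile rests on the values that drew attention to the list, so it is no independent evidence. The random lists also drew genes singly and did not allow for neighbouring members. The pattern was not confined to cardiac factors. Of the 10 other fixed lists compared, 3, 2 and 1 also lay above the central 95% under the 3 matchings, skeletal muscle regulators under each. Fewer cardiomyocytes in the pool of replicate 2 may be a candidate and stays open. A second list of 54 cardiomyocyte genes was chosen before its values were seen. Its 26 covered members did not rise in replicate 2 (14 higher, 12 lower, mean -0.0262 points). They still lay at the 99.1 percentile of matched lists, whose mean was -4.36. The percentile was 99.6 and 96.5 with the other matchings, 99.9 with TSS ± 10 kb and 81.7 with a −log10 q of 2 or more. The fixed contraction list had 4 members higher and 6 lower and a mean of 0.556 points. Its percentile was 98.2 (97.2 and 95.7 with the other matchings, 98.1 with TSS ± 10 kb, 86.2 with a −log10 q of 2 or more). The lists of other cell types did not decide. Endothelial, fibroblast and blood lists lay at 61.3, 93.3 and 40.3. With TSS ± 10 kb the blood list lay at 7.88 (0.0 among other transcription factors), with 0 of 11 members higher in replicate 2. In that setting the endothelial and fibroblast lists lay at 91.3 and 89.3. With a −log10 q of 2 or more the endothelial list lay at 96.9. These percentiles describe 2 libraries of 1 group and leave this explanation undecided.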
